A study of Folsomia candida with 16 samples.

How the data were processed

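RNA of the springtail Folsomia candida was measured on 16 two-colour Agilent arrays. Each array held 1 pool of desiccated animals (98.2% relative humidity) in one dye and 1 pool of reference animals (100% relative humidity) kept for the same time in the other dye, with 4 arrays at each of 8, 27, 53 and 174 h. Replicates 1 and 3 of each time carried the desiccated pool in Cy5 and replicates 2 and 4 carried it in Cy3, per the labels. Pools held about 25 animals each and 500 ng of total RNA was amplified and labelled, per the labels' protocols. The design text calls the replicates biological, and each of the 32 channels held RNA of its own pool.

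The scanner files hold spot intensity values in both channels, with local background, outlier, saturation and brightness flags, made with Agilent Feature Extraction 9.1.3.1 per the file headers. The same files hold the log10 ratio of Cy5 over Cy3 of the scanner software's processed intensities, per the file headers. A deposited table of the whole series holds the authors' log2 ratios, and limma 2.9.1 is named in the submitters' processing notes. That table does not state scale, centring or direction. Set against the scanner ratios, its columns correlated positively on the arrays with the desiccated pool in Cy5 and negatively on the others, so it is already turned to desiccated over reference. Its columns had medians between -0.02 and 0.01, and its normalization steps stay unknown. The values correlated with the ratios computed here at r between 0.997 and 0.999 over the arrays, and they were used only as an alternative.

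From the scanner files, mean spot signals were corrected with the local median background by normexp with an offset of 50, and the log2 ratios were normalized within each array by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). The 465 positive and 79 negative control spots and spots with an outlier flag were left out. The array carries 5131 probes of 60 bases, each printed as 2 spots with an identifier of its own, and the mean of the usable spots was taken. A probe was kept where it was well above background on every array of at least 1 of the 8 groups of time and humidity, in the channel holding that group's RNA. This left 3394 probes, and 1737 were left out as dim. Ratios were turned to desiccated over reference on all arrays. The offset pulls the ratios of dim spots toward 0, so folds of weak transcripts are understated.

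One linear model per transcript (lmFit and eBayes of limma) was fitted to all 16 arrays, with 1 mean ratio for each time and 1 dye term, and the times shared one estimate of the spread. Each time's ratio, their mean, the pairwise differences and a moderated F test of the 3 differences among the 4 times came from that fit. A transcript is called changed at a Benjamini-Hochberg adjusted p under 0.05 over the transcripts tested. The time course of the reference animals was tested by limma's separate channel fit after Aquantile normalization between arrays, with an intraspot correlation of 0.459 and a dye term. On simulated ratios with the real spreads and dye effects, the fit recovered 61 of 67 transcripts changed by 0.5 on the log2 scale at 174 h, 63 of 67 changed by 1 and 65 of 66 changed by 2, and it called 6 of 3194 unchanged ones. The separate channel fit recovered 55 of 67 simulated reference changes of 0.5, 64 of 67 of 1 and 62 of 66 of 2, and called 9 of 3194 unchanged ones. The simulated noise was independent between transcripts, with 1 spread per transcript over all arrays. Arrays of unequal quality and deviations shared between transcripts were therefore not covered.

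Where a probe was not well above background on any array of a group, its ratio is given as a bound. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, per channel after loess and Aquantile normalization. No gene names stand in the array files, and 0 of the 5131 identifiers matched the reference gene table of assembly ASM221717v1 with its 27231 genes. Transcripts are therefore reported by the probe identifier and the probe's sequence, without coordinates, and the 23 gene lists fixed before the data were examined could not be tested. The rule for the transcripts named here, also fixed then, takes those with the largest rises and falls at a time among the transcripts called and changed the same way on all 4 arrays, and allows at most 2 identifiers without a gene name that rose and 2 that fell. Its parts for transcripts with a gene name could not be used, and the limit on unnamed ones was applied to each time. For the reference time course they are those with the largest change from 53 to 174 h among the transcripts called by the F test and for that difference. This ranking of the reference transcripts was chosen after the data were seen. No tested probe shares 25 bases on the same strand with another probe, and 2 share 25 bases with the opposite strand of another.

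The arrays lay on 8 slides of 2 arrays. A slide held 8 and 27 h or 53 and 174 h of one replicate number, and the slides were scanned on 4 days. Scan day 3 held replicates 2 and 3 of every time, so it has 2 arrays of each time with opposite dyes. The other days held 1 array of a time, for which only the direction can be compared. The number of arrays limits the precision. The SD between duplicate spots ranged from 0.05 to 0.23 log2 units over the arrays, and 55.5% to 71.8% of the transcripts were well above background in a channel. Alternatives fixed before the data were examined changed the background correction, the normalization within and between arrays, the filter on dim probes, the dye term, array weights, slide and replicate blocks, the source of the values and the arrays in the fit. Scan day as a block, scan day 3 alone, slide as a fixed block, the fit without the 8 h arrays and the settings tried on the places of the pools were added after the data had been seen.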

Results

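Folsomia candida is a soil springtail that reproduces by parthenogenesis and loses water readily through its cuticle. The study asked how its transcripts respond to a mild drop in air humidity over hours to days. Pools of about 25 animals, 25 to 27 days old, were kept at 98.2% relative humidity (desiccated) or 100% relative humidity (reference) and frozen after 8, 27, 53 or 174 h. Each of the 16 arrays compared 1 desiccated with 1 reference pool of the same time, with 4 arrays per time and the dyes swapped between replicates. The median spot signal ranged from 190 to 323 in Cy5, over a median local background of 88 to 94, and from 75.9 to 112 in Cy3, over a background of 44 to 52. Of 5131 transcripts on the array, 3394 were bright enough to be tested.

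The log2 ratios became more alike between replicates with time. Across the tested transcripts, which are not independent replicates, the correlation between arrays of one time ranged from -0.01 to 0.63 at 8 h, from 0.38 to 0.67 at 27 h, from 0.73 to 0.83 at 53 h and from 0.87 to 0.91 at 174 h. The arrays of 27 h resembled those of 53 h, with a mean r of 0.49 over 16 pairs. Between 27 and 174 h the mean r was -0.08 and the lowest was -0.43, for replicate 4 of 27 h. Arrays of 8 and 27 h reached -0.48. The dyes are stated for every array, so the direction of the ratios was kept.

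**Figure D1:**
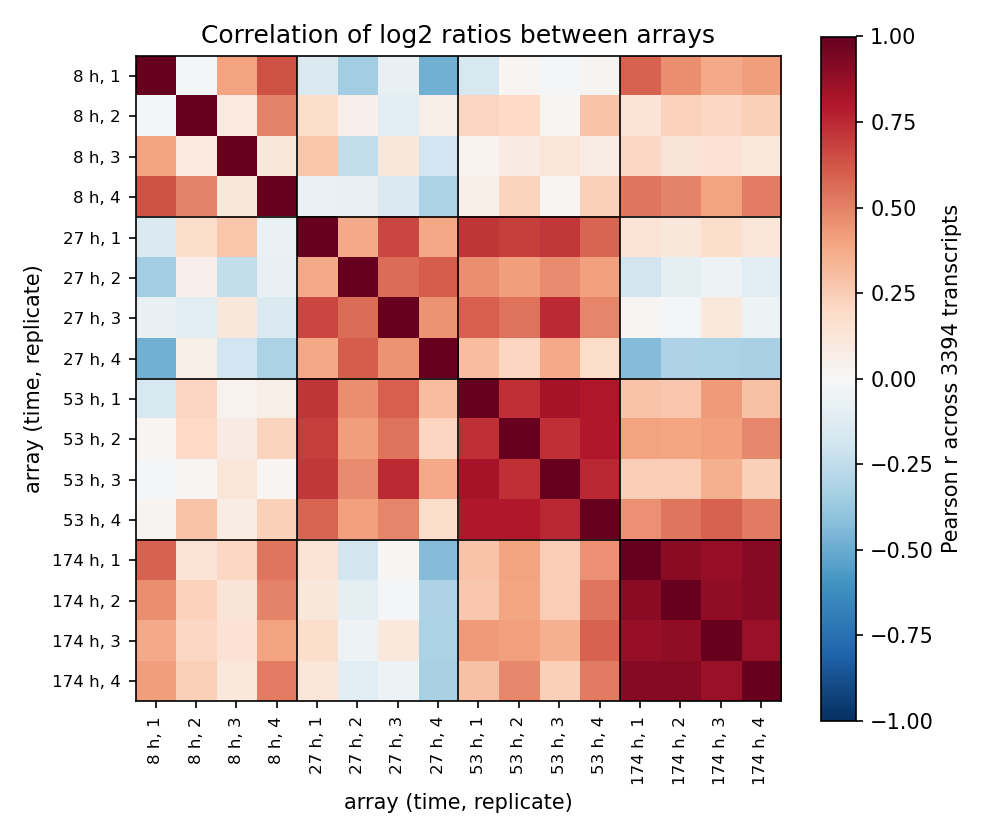
Pearson correlation across the tested transcripts between the log2 ratios (desiccated over reference) of all pairs of the 16 arrays, ordered by time and replicate, on a colour scale from -1 (blue) to 1 (red). The 174 h arrays correlate with one another at 0.87 to 0.91, and the 8 h arrays at -0.01 to 0.63.

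After 8 h, 208 transcripts differed between desiccated and reference animals, 168 higher and 40 lower. The called rises were larger, with a median log2 ratio of 0.52 against -0.31 among the falls, and 28 rises but 2 falls exceeded 2-fold. Among the called transcripts that moved the same way on all 4 arrays, the largest rise was that of Fcc04434C1 (probe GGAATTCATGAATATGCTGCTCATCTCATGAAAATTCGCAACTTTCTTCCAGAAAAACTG), at a log2 ratio of 2.73 ± 1.54 (SD, n = 4; adjusted p = 0.0138). Fcc02517C1 (probe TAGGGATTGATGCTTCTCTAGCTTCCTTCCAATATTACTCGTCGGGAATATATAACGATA) followed at 2.37 ± 0.47 (adjusted p = 0.000604) and lay at 0.05 ± 0.09 at 27 h. Fcc06180 (probe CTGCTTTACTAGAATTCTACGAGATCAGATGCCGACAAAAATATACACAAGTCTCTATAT) had the largest fall among these, at -1.29 ± 0.23 (adjusted p = 7.35e-05), and stood at -2.04 ± 0.22 at 27 h and 0.03 ± 0.23 at 53 h. The ratio of Fcc00069 (probe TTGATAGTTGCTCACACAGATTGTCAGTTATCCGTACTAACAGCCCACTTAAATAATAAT) was -0.91 ± 0.46 (adjusted p = 0.0072), and it was lower at every time, down to -1.48 ± 0.25 at 53 h. The 8 h count fell to 130, 77, 137 and 51 without replicates 1, 2, 3 and 4 of 8 h, and Fcc04434C1 and Fcc00069 were no longer called without replicate 2 or 4. With the arrays scaled to one spread it was 567 (361 higher, 206 lower), with array weights 804 (458 higher, 346 lower), and within scan day 3, with 2 arrays of each time, it was 6, all 4 named transcripts then missing the threshold at log2 ratios of 2.25, 2.42, -1.35 and -0.99.

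After 27 h, 1141 transcripts differed, 552 higher and 589 lower, with median log2 ratios of 0.39 and -0.37. Among these, 65 rises and 55 falls exceeded 2-fold. Fcc00354C1 (probe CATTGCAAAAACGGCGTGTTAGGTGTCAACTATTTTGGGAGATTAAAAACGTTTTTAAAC) rose the most among those that moved the same way on all 4 arrays, at 3.45 ± 1.66 (SD, n = 4; adjusted p = 0.0185), with 2 of the 4 reference pools well above background. Fcc05841 (probe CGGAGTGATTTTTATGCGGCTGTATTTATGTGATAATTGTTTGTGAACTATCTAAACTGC) stood at 3.24 ± 1.70 (adjusted p = 0.00864), also with 2 of 4 reference pools well above background. At 8 h the same transcript was lower, at -3.80 ± 3.19, with 3 of 4 arrays in that direction (adjusted p = 0.0163) and 1 of 4 desiccated pools well above background. That p rests on the spread shared by all times (SE 0.82), while the 8 h arrays ranged from -6.72 to 0.65. Fcc04297 (probe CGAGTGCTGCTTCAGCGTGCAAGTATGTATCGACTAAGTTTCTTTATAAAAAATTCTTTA) fell to -3.33 ± 0.78 (adjusted p = 9.48e-07) and lay at -3.05 ± 0.30 at 53 h. Fcc00207 (probe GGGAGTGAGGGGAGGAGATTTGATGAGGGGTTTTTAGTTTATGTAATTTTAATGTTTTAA) was at -2.68 ± 1.96 (adjusted p = 0.00129). Without replicate 3 of 27 h the count was 747, with median centring in place of loess 598, with the 4 arrays of 27 h alone 619, and within scan day 3 it was 446. Fcc00354C1 lost its call without replicate 3 or 4 of 27 h, with array weights and within scan day 3, and Fcc05841 lost it within scan day 3, where the ratios were 2.81 and 2.67.

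After 53 h, 1569 transcripts differed, 783 higher and 786 lower, and 122 rises and 114 falls exceeded 2-fold. Of the transcripts with one direction on all 4 arrays, Fcc04434C1 again had the largest rise, now at 4.18 ± 0.40 (SD, n = 4; adjusted p = 7.53e-05). Fcc00101C1 (probe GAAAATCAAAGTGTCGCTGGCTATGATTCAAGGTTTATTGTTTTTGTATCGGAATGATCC) was higher by 3.75 ± 0.70 (adjusted p = 5.06e-06). Fcc00207 was lower, at -4.46 ± 1.47 (adjusted p = 1.39e-05). Fcc00171C1 (probe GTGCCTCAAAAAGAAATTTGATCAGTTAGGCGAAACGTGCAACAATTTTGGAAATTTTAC) was lower at -3.84 ± 1.56 (adjusted p = 1.54e-05), with 2 of the 4 desiccated pools well above background. The ratio of Fcc00171C1 was -5.97 with Agilent's processed signals and -2.70 within scan day 3. The count at 53 h was 980 with median centring and 643 within scan day 3.

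After 174 h, 2248 transcripts differed, 66.2% of those tested, with 1068 higher and 1180 lower. The falls were larger than the rises. Of the called transcripts, 283 fell by over 2-fold and 104 by over 4-fold, against 118 and 21 rises, and the median fold was 1.41 among falls and 1.35 among rises. Fcc04611 (probe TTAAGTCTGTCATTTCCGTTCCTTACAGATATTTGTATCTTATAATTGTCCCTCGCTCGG) was the most raised of those with one direction on all 4 arrays, at 5.18 ± 0.60 (SD, n = 4; adjusted p = 6.27e-07), or 3.82 with the arrays scaled to one spread and 6.49 with Agilent's processed signals. Fcc01307C1 (probe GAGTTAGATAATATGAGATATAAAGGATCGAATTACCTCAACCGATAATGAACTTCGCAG) was higher by 4.57 ± 0.12 (adjusted p = 9.53e-07), after 2.89 ± 0.96 at 53 h. Fcc05079C1 (probe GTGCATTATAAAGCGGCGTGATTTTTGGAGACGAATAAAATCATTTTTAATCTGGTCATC) was the most lowered of these, at -8.22 ± 0.75 (adjusted p = 4.21e-05). Its probe was saturated in 1 of the 4 reference pools, so the level of that pool is a lower bound. The ratio was -6.05 with the arrays scaled to one spread and -9.38 with Agilent's processed signals. Fcc02721 (probe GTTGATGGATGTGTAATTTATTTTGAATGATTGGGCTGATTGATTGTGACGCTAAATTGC) was at -6.66 ± 0.26 (adjusted p = 3.62e-05). In Fcc00354C1, which had risen at 27 h, the desiccated pools of 174 h were not well above background and the reference pools were at least 25.5-fold brighter (adjusted p = 0.000752). With Agilent's processed signals 1291 were higher and 1067 lower, and with median centring 961 and 872. With only probes above background in all 32 channels, 867 were higher and 807 lower. Within scan day 3 the count was 1399.

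**Figure D2:**
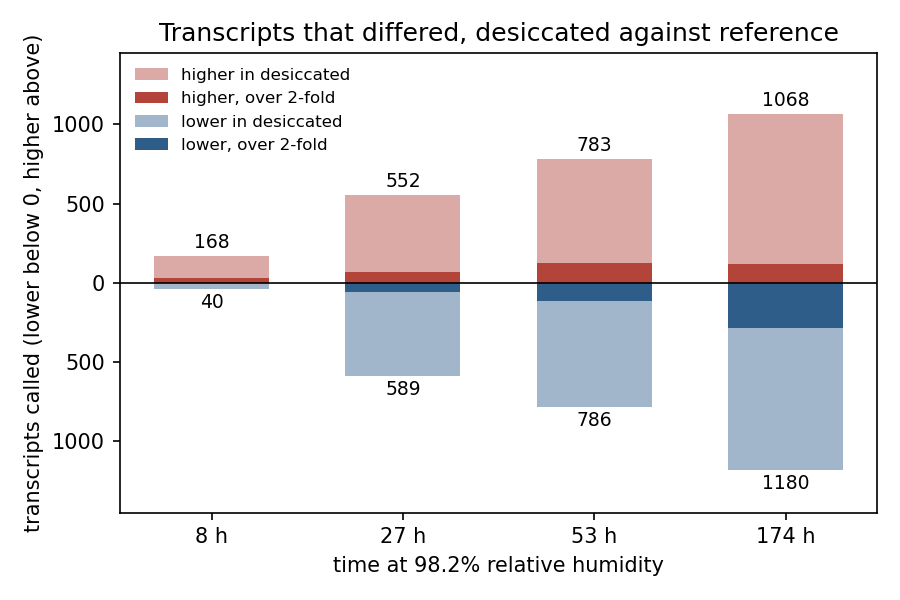
Number of transcripts called at an adjusted p under 0.05 at each time, higher in desiccated animals (red, above 0) or lower (blue, below 0), with those over 2-fold in the darker shade. Calls rose from 208 at 8 h to 2248 at 174 h, and falls over 2-fold were 283 at 174 h against 118 rises.

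On average over the 4 times, 2181 transcripts differed, 1056 higher and 1125 lower, or 1167 and 1028 with Agilent's processed signals. These mean effects were small, with a median log2 ratio of 0.21 among those higher and -0.23 among those lower. Over 2-fold lay 39 of the rises and 69 of the falls. At least 1 time called 2833 transcripts (83.5% of those tested), while 56 were called at all 4 times. Within scan day 3 the average count was 1377.

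The effect of desiccation differed between the times for 2255 transcripts (66.4%) by the F test. From 8 to 27 h, 729 effects differed (319 toward higher, 410 toward lower). That count was 342 with median centring, 1166 with array weights and 98 within scan day 3. From 53 to 174 h, 1598 effects differed (743 and 855, or 943 and 729 with Agilent's processed signals, 559 and 477 with median centring and 553 and 528 with the arrays scaled to one spread). From 27 to 53 h there were 125. The effects of 27 and 53 h correlated across transcripts at r = 0.70. Of the 838 transcripts called at both times, 99.0% went the same way, with 399 higher at both where independent lists would share 127 and 431 lower at both where they would share 136. Between 53 and 174 h r was 0.44, and 199 of 1099 transcripts called at both had turned direction. Between 27 and 174 h r was -0.08 and rho 0.06. Of the 781 called at both, 222 were higher at both where independent lists would share 174 and 232 lower at both where 205 would, while 166 went from higher to lower where 192 would and 161 from lower to higher where 185 would. The effects of 8 h correlated at 0.52 with those of 174 h (0.25 within scan day 3) and at -0.18 (rho 0.0071) with those of 27 h. Of the 1569 transcripts called at 53 h, 554 moved toward or past 0 by 174 h, 215 moved further from it and 800 had no called difference. Selection on the 53 h arrays favours movement toward 0 here. Of the transcripts called at 174 h, 1209 had a called difference from 53 h in the direction of their 174 h effect, with the opposite selection. This count takes in transcripts that crossed 0, whether or not they ended further from it.

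The ratios of single transcripts followed different courses. Fcc04434C1 went from 4.18 at 53 h to -1.80 ± 0.62 (SD, n = 4; adjusted p = 0.0141) at 174 h. Fcc04297 had a ratio of 0.42 ± 0.20 at 8 h (adjusted p = 0.264) and was still lower at 174 h, at -0.78 ± 0.23 (adjusted p = 0.00534). From 53 to 174 h its mean log2 level went from 8.88 to 8.98 in desiccated pools and from 11.93 to 9.76 in reference pools. The ratio of Fcc00207 deepened from -1.05 ± 0.75 at 8 h (adjusted p = 0.24) to -6.18 ± 0.94 at 174 h (adjusted p = 4.66e-07). Its desiccated pools had mean log2 levels of 11.07, 7.06, 6.78 and 7.01 at 8, 27, 53 and 174 h. Its reference pools had 12.12, 9.74, 11.24 and 13.19, so after 27 h the ratio deepened mainly through the reference level. Of the 14 named transcripts, 13 passed the F test of the times, and Fcc00069 did not (adjusted p = 0.114). The difference between 53 and 27 h depended on the processing and on single arrays. It had 19 calls with median centring, 39 without the dye term and 623 with array weights. From 125, the count went to 77 without replicate 1 and 73 without replicate 2 of 8 h, 378, 7, 60 and 5 without replicates 1 to 4 of 27 h, and 4, 53 and 5 without replicates 1, 2 and 4 of 53 h. The F test called 1485 transcripts with median centring and 862 within scan day 3.

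**Figure D3:**
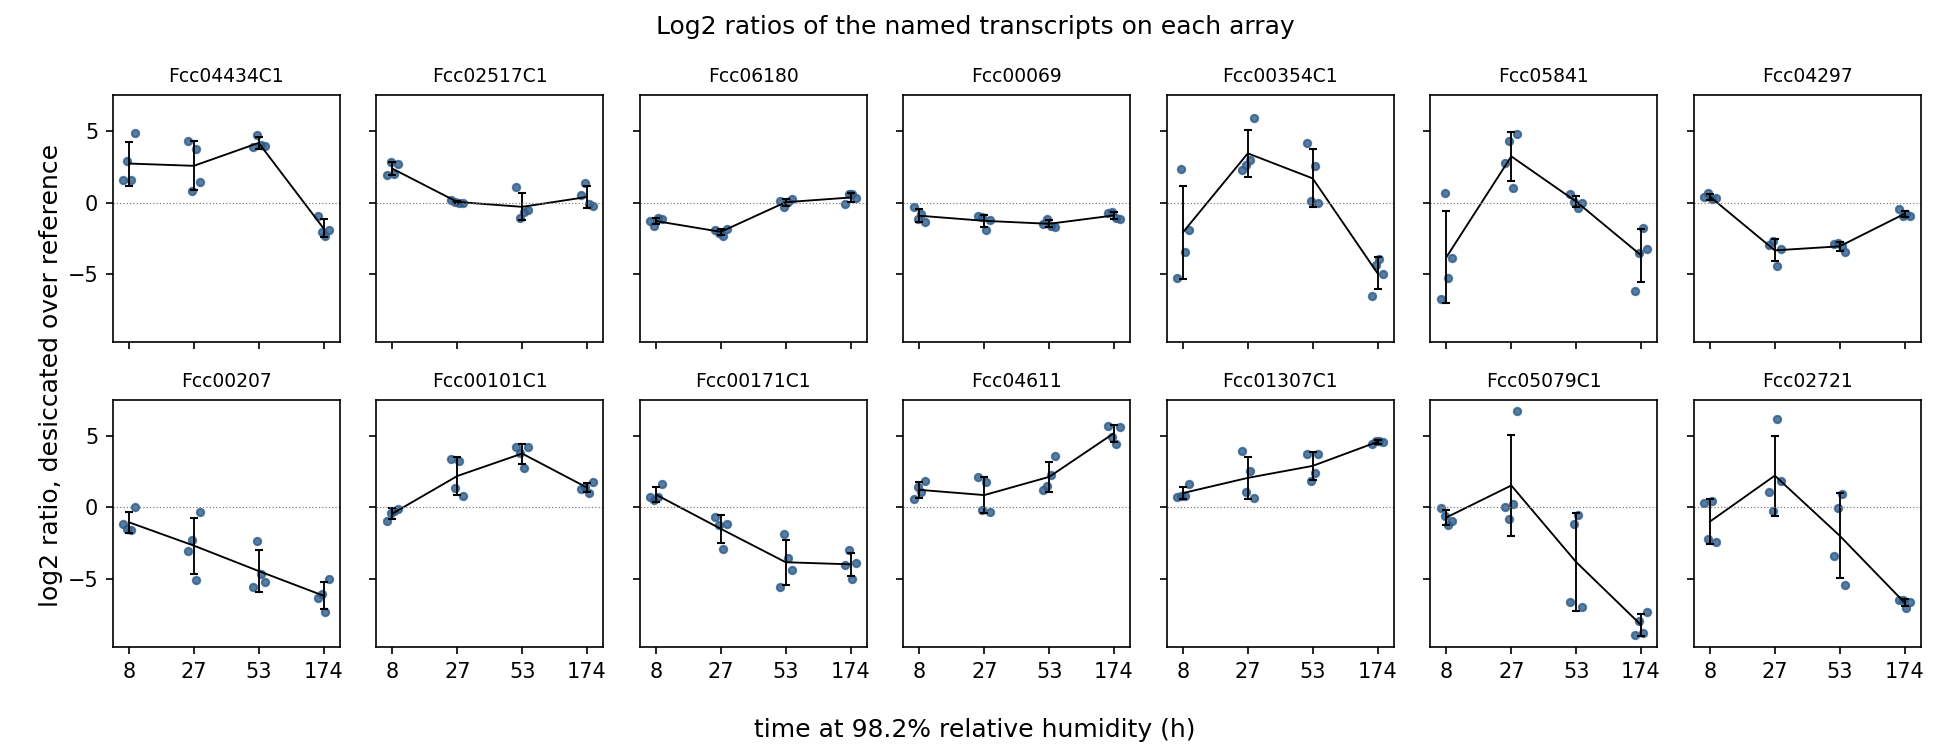
Log2 ratio (desiccated over reference) of the named transcripts on each array against time in hours. Points are arrays, and the line and bars give the mean and SD of the 4 arrays. The ratio of Fcc04611 climbs to 5.18 at 174 h, that of Fcc05079C1 drops to -8.22, and that of Fcc04434C1 changes sign between 53 and 174 h. From 53 to 174 h the mean log2 level of Fcc04611 went from 10.47 to 7.08 in reference pools and from 12.59 to 12.26 in desiccated pools. That of Fcc05079C1 went from 10.47 to 15.35 and from 6.64 to 7.13, and that of Fcc04434C1 from 8.28 to 10.07 and from 12.46 to 8.28. The probe of Fcc05079C1 was saturated in 1 reference pool of 174 h and in 1 desiccated and 2 reference pools of 8 h.

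The reference pools were frozen at the same times and give a time course without desiccation. Times lie on different arrays, so an array batch that followed time cannot be told apart from this course. The F test and the differences from 27 to 53 h and from 8 to 174 h also cross different slides. In them, 1963 transcripts (57.8%) differed between times. From 8 to 27 h 351 rose and 251 fell, from 27 to 53 h 45 rose and 38 fell (22 without replicate 4 and 50 without replicate 1 or 2 of 53 h, 129, 43 and 28 without replicates 1, 2 and 4 of 27 h, in all), and from 53 to 174 h 657 rose and 583 fell, the last split being 483 and 763 with quantile normalization of all channels. Between 8 and 174 h 806 were higher and 548 lower at 174 h, or 643 and 671 with quantile normalization. Among transcripts called both from 8 to 27 h and from 53 to 174 h, which lie on different arrays, 287 of 319 moved in opposite directions. Those that rose and later fell numbered 168 where independent lists would share 60.3, and 119 fell and later rose where 48.6 would. In desiccated pools 212 of 360 moved in opposite directions, 160 rising and later falling where 79.3 would and 52 falling and later rising where 57.3 would.

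Fcc04350 (probe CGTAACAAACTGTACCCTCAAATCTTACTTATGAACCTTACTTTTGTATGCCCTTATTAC) was not well above background in any reference pool of 53 h and stood at a log2 level of 13.18 ± 1.27 (SD, n = 4) in those of 174 h (adjusted p = 0.00215). Fcc04479 (probe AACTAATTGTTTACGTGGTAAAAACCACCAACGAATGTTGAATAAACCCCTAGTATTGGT) rose from 6.57 ± 0.12, with 1 of 4 pools well above background, to 13.19 ± 1.10 (adjusted p = 0.000759), while the desiccated pools of 174 h were at 6.99 ± 0.77. Fcc04611 fell in reference pools from 10.47 ± 1.47 to 7.08 ± 0.74 (adjusted p = 5.46e-05) and was at 12.26 ± 0.48 in desiccated pools of 174 h. Fcc02841 (probe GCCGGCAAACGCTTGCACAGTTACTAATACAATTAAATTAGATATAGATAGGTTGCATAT) fell from 10.95 ± 0.36 to 8.38 ± 0.47 (adjusted p = 1.85e-09).

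Each pool was placed along the reference animals' change from 53 h (0) to 174 h (1), with the axis taken from arrays other than its own. Transcripts with large reference changes weigh most in this place. Reference pools of 53 and 174 h set the axis, so those groups lie near 0 and 1 by the way it is built. The reference pools lay at 0.48 ± 0.13 (SD, n = 4) at 8 h, 0.02 ± 0.21 at 27 h, 0.04 ± 0.17 at 53 h and 0.96 ± 0.23 at 174 h. The desiccated pools lay at 0.17 ± 0.14, 0.28 ± 0.19, -0.04 ± 0.16 and -0.02 ± 0.17. The desiccated pool was lower than its reference pool on 4 of 4 arrays at 8 h and at 174 h, on 2 of 4 at 53 h and on 0 of 4 at 27 h. Durations lie on different arrays, but 8 and 27 h shared slides, as did 53 and 174 h. With slide as a fixed block 844 reference transcripts differed from 8 to 27 h and 1572 from 53 to 174 h, against 602 and 1240.

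**Figure D4:**
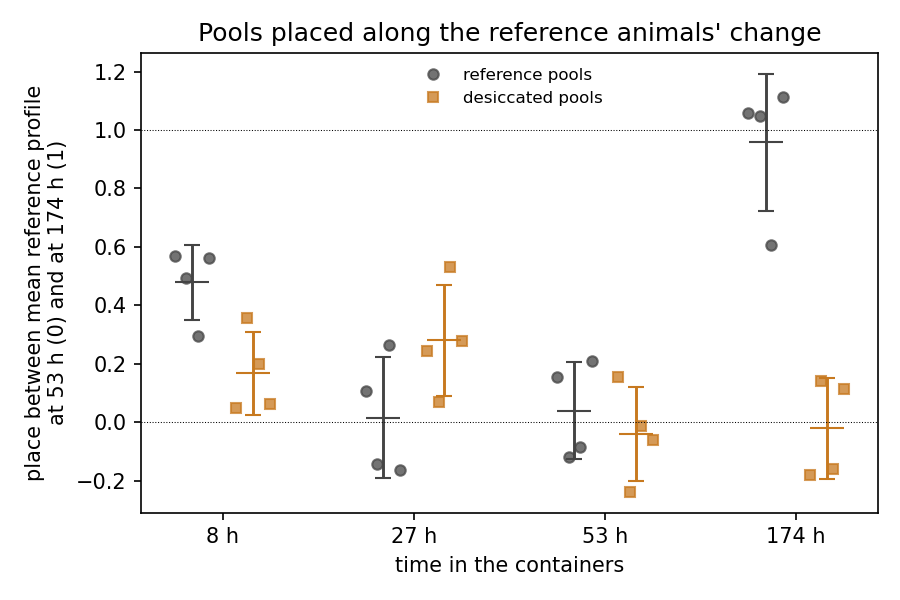
Place of each pool between the mean reference profile of 53 h (0) and that of 174 h (1), in units of that change, for reference pools (circles) and desiccated pools (squares) at each time. Bars give mean and SD of 4 pools, and at 174 h the reference pools average 0.96 and the desiccated pools -0.02. Transcripts with large reference changes weigh most in the place.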

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

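The tests of dye, slides and scan day in this part were chosen after the results had been seen, and the test within bins of brightness was chosen before its own result was seen.

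The effect of desiccation differed between times for 2255 transcripts, with 729 differences from 8 to 27 h, 125 from 27 to 53 h, 1598 from 53 to 174 h and 1581 from 8 to 174 h. Median centring gave 19 from 27 to 53 h. From 8 to 174 h it gave 1024 (589 higher and 435 lower, against 747 and 834), and scaling the arrays gave 950. With slide as a fixed block, 561 differences from 8 to 27 h and 1413 from 53 to 174 h were left, so slides do not account for these, which lie within slides. A shift between the sets of slides would enter the differences from 27 to 53 h as it enters those from 8 to 174 h, but the slope of the first on the second across the 1581 transcripts was 0.33 (0.28 to 0.38 with single arrays left out), which leaves open a slide part of that size and all of the 125. Scan day does not account for the contrast of 27 and 174 h, since within scan day 3 the effects of 27 and 174 h had a correlation of -0.00237 across transcripts, where 27 and 53 h had 0.69. A true difference between durations stays open as the biological explanation.

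Among the named transcripts, the F test of the times gave an adjusted p of 0.000228 for Fcc04434C1, 0.000738 for Fcc02517C1, 2.32e-06 for Fcc06180, 0.000877 for Fcc00354C1, 0.000445 for Fcc05841, 2.72e-06 for Fcc04297 and 0.000254 for Fcc00207. It gave 0.000161 for Fcc00101C1, 7.26e-05 for Fcc00171C1, 0.000242 for Fcc04611, 0.00102 for Fcc01307C1, 0.00112 for Fcc05079C1 and 0.000587 for Fcc02721.

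The arrays of 8 h did not resemble one another evenly, since arrays 1 and 4 correlated with each other at 0.63 and with the 174 h effect at 0.49 and 0.51, while arrays 2 and 3 correlated with it at 0.21 and 0.15. Arrays 1 and 4 carry opposite dyes, so a dye bias would have made their correlation negative, but pairs with the same dyes (1 and 3 at 0.40, 2 and 4 at 0.50) were more alike than the other pairs with opposite dyes (-0.01, 0.10 and 0.11), so dye stays open for the rest of the unevenness. The 27 h arrays on the same slides, scanned on the same days, correlated with the 174 h effect at 0.14 and -0.36, which a slide or scan day effect on both arrays of a slide would not give. Within 5 bins of brightness the correlation between arrays 1 and 4 was at least 0.46. Differences between pools of one treatment stay open and were not tested, because the design names nothing that sets these pools apart.

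In 5 of 92 groups of 4 values, 1 value lay far from the others, and chance gives about 4.6 such groups. The SD between duplicate spots was 0.183 on replicate 3 of 27 h, against 0.0543 to 0.0613 on the other arrays of that time. The median Cy5 signal was 323 on replicate 4 of 174 h, against 190 to 200 on the others. The log2 ratio of Fcc01307C1 was 1.66 on replicate 4 of 8 h, against 0.70 to 0.82. That of Fcc05079C1 was 6.74 on replicate 4 of 27 h, against -0.85 to 0.20. The reference pool of replicate 3 at 174 h lay at 0.608 on the axis from 53 to 174 h, against 1.05 to 1.11.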

How the results depend on the processing

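Background subtraction, the dim probe filter, slide or scan day as a random block and the series table moved none of these counts by over 1.5 times. The filter did move their split. With only the 2481 probes above background in all 32 channels, 867 were higher and 807 lower at 174 h, against 1068 and 1180. The difference from 53 to 174 h then had 615 and 592, against 743 and 855, and the mean over times 833 and 817, against 1056 and 1125. Median centring in place of loess gave 76 calls at 8 h, 598 at 27 h and 980 at 53 h, 1485 by the F test of times, 342 from 8 to 27 h, 19 (13 higher) from 27 to 53 h, 1036 from 53 to 174 h and 1024 (589 higher, 435 lower, against 747 and 834) from 8 to 174 h. Scaling the arrays after loess gave 567 calls at 8 h, of which 63.7% were higher against 80.8%, and 950 from 8 to 174 h. Agilent's processed signals without loess gave 206 calls from 27 to 53 h. Leaving out the dye term gave 131 at 8 h and 39 from 27 to 53 h. Array weights gave 804 at 8 h (458 higher, 346 lower), 1166 from 8 to 27 h and 623 from 27 to 53 h. With only the arrays of one time in the fit, 8 h had 339 calls and 27 h 619. The cause of these shifts was not tested.

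Added after the data had been seen, the 8 arrays of scan day 3 gave 6 calls at 8 h, 446 at 27 h, 643 at 53 h, 1399 at 174 h, 1377 on average and 862 by the F test, from fewer arrays. Of differences they gave 98 from 8 to 27 h, 594 from 53 to 174 h, 674 from 8 to 174 h and, with limma, 0 from 27 to 53 h, where 477 had an unadjusted p under 0.05. On the other scan days, with 1 array of a time that was also part of the fit behind the calls, 91.0% to 98.7% of the 27, 53 and 174 h calls and at least 97.6% of the 8 h calls kept their direction. Without the 8 h arrays 14 transcripts differed from 27 to 53 h.

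Leaving out each array gave 51 to 272 calls at 8 h, 747 to 1162 at 27 h and 4 to 378 from 27 to 53 h, and in reference animals 22 to 129 from 27 to 53 h. The lowest came in turn without replicate 4 of 8 h, replicate 3 of 27 h, replicate 1 of 53 h and replicate 4 of 53 h. The reference count from 27 to 53 h, 83 with all arrays, was 129, 43 and 28 without replicates 1, 2 and 4 of 27 h and 50, 50 and 22 without replicates 1, 2 and 4 of 53 h. Quantile normalization of all channels gave 38.8% higher among the reference calls from 53 to 174 h, against 53.0%, and 48.9% from 8 to 174 h, against 59.5%.

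In the log2 ratios, arrays of one replicate number were not more alike than others. Deviations of same-numbered arrays correlated from -0.54 to 0.44, with 2 of 24 pairs over 0.1, and 1 of 16 arrays was closest to its own number. They were not unrelated throughout. Between 8 and 27 h, which shared slides, replicates 1 to 4 gave -0.31, -0.31, -0.21 and -0.42. Between 53 and 174 h, which also did, they gave -0.20, -0.10, 0.09 and -0.22. The replicate block gave 239 calls at 8 h and 2268 at 174 h. In reference animals it gave 2196 by the F test, against 1963 without it, and 135 from 27 to 53 h, against 83. Deviations of the channel levels were not compared, so a pairing of the reference levels by replicate number stays open.

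Of 472 recomputed ratios of the 16 named values, 459 kept direction and threshold, 13 missed the threshold and 0 changed direction. Many of these settings left out an array of another time, which can hardly move the ratio, and the values were picked for large changes on these arrays. In every setting where they were tested, 10 of the 16 values passed the threshold. Their sizes moved at every time. At 174 h scaling the arrays gave 3.82 for Fcc04611, 3.38 for Fcc01307C1, -6.05 for Fcc05079C1 and -4.91 for Fcc02721, and Agilent's processed signals gave 6.49, 5.68, -9.38 and -7.57. Over the settings, Fcc02517C1 at 8 h ranged from 2.21 to 3.59 and Fcc00354C1 at 27 h from 2.71 to 5.01. Fcc05841 at 27 h ranged from 2.67 to 4.81 and Fcc00171C1 at 53 h from -5.97 to -2.70. Taking the median over probes, or each probe alone, was not run since each identifier has 1 probe, and the gene list alternatives were not run for want of names. Signal over background limits dim transcripts, of which 1737 were left out.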

Other observations

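The tests on shared reference pools, probe GC content and the course of desiccated animals in this part, and the look at the spread between pools, were chosen after the results had been seen. The test within bins of brightness and the counts over other splits of the arrays were set before their own results were seen.

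A few transcripts differed widely between pools of the same group. The SD between the 4 pools exceeded 1.5 log2 units for 10 transcripts in reference pools of 53 h, where the median SD over all tested transcripts was 0.13. All 10 were among those lower in desiccated animals at 174 h. In reference pools of 27 h there were 19 such transcripts, 16 of them lower at 174 h, and in desiccated pools of 27 h there were 22, with 19 lower at 174 h. Fcc05079C1 was chosen as the example after its values were seen. Its reference pools of 53 h had log2 levels of 12.23, 8.45, 6.85 and 14.37, and those of 174 h lay between 15.11 and 15.76. In desiccated pools it went from 13.57 to 14.99 at 8 h to between 6.67 and 7.40 at 174 h. Its probe was saturated in 1 reference pool of 174 h and 1 desiccated pool of 8 h, so the levels in those pools are lower bounds.

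The 174 h effect followed the reference animals' own time course. Transcripts that fell in reference animals from 8 to 27 h were lower in desiccated animals at 174 h in 179 of 251 cases, where independent lists would share 87.3, and 174 of the 351 that rose were higher, where 110 would be. Rising from 8 to 27 h and falling from 53 to 174 h was not particular to reference animals, since 160 transcripts did so in desiccated animals where 79.3 would by independent lists, but falling and then rising was seen in 52 there where 57.3 would.

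The correlation of the 174 h effect with the reference change from 8 to 27 h was 0.51 across transcripts, although the 8 and 27 h arrays hold none of the 174 h pools, so the shared reference pools at 174 h do not account for it. It was at least 0.37 in each of 5 bins of brightness and 0.52 among the 2405 probes with a GC content of exactly 35%, which argues against brightness and probe GC content. A hypothesis is that reference animals passed through a recurring phase near 8 and 174 h, such as a stage of the moulting and egg-laying cycle of adult springtails, and that desiccated animals may not have entered it by 174 h. Along the reference change from 53 to 174 h, estimated in other replicates, desiccated animals moved by at most 0.294 of the reference change over 6 splits of the replicates (the lowest was -0.326), as this hypothesis needs, while 938 transcripts did change in them from 53 to 174 h. Transcripts with large reference changes weigh most in that share. Moults and eggs were not analysed here, so which process it is stays open, and the pattern was found and tested on the same arrays.

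The 8 h effect correlated at -0.66 with the reference change from 53 to 174 h and the 27 h effect at 0.40, both measured on other arrays. The reference changes from 8 to 27 h and from 53 to 174 h ran in opposite directions (r = -0.60). By these correlations the effects of 8 and 174 h lay on the same side along this reference change and that of 27 h on the other. They are Pearson correlations, which transcripts with large changes weigh on most, and rank correlations with the reference change were not computed. Between the effects of 8 and 27 h, r was -0.18 but rho 0.0071. How widely the pattern holds over the transcripts therefore stays open. Over all transcripts the effects of 27 and 174 h were not opposed, with rho = 0.06. The 53 h effect correlated at 0.02 with the reference change from 8 to 27 h.

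Other splits of the arrays were counted for each number of calls. Exchanging desiccated and reference pools within the 4 arrays of a time makes 8 splits, too few for a share under 0.05, the real one included. The real counts were 208, 1141, 1569 and 2248 from 8 to 174 h, and the highest of the other splits gave 1, 1, 1 and 0. Chance can be excluded for the mean over times, where 1 of 100 splits reached 2181 and the highest other gave 947. For the F test of times, 1 of 100 reached 2255 and the highest other gave 2. This excludes chance only among splits that take no account of slides. For the differences between times, 1 of 35 splits reached each real count, the lowest share that 35 splits can give. That share is under 0.05 for each difference taken alone. It was not corrected for the number of differences, and the splits take no account of slides, so chance is not excluded. The differences from 8 to 27 h and from 53 to 174 h lie within slides, where exchanges on each slide make only 8 of these 35 splits, too few for a share under 0.05. With slide as a random block, the fitted correlation of the deviations of the log2 ratios within a slide was -0.0508. It was not computed for the reference levels. The highest others were 6 against 729 from 8 to 27 h, 47 against 125 from 27 to 53 h, 1 against 1598 from 53 to 174 h and 2 against 1581 from 8 to 174 h. In reference animals 1 of 100 splits reached 1963 by the F test, with 314 the highest other. There 1 of 35 reached 602 from 8 to 27 h (highest other 8), 83 from 27 to 53 h (29), 1240 from 53 to 174 h (225) and 1354 from 8 to 174 h (297).

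The platform's 10 E1A spike-in control probes, which no comparison used, shifted together on each array after normalization, by -0.96 to 1.23 log2 units of Cy5 over Cy3 around each probe's mean, with an SD between probes of at most 0.34. Turned to desiccated over reference the shift was 0.39 ± 0.53 (SD, n = 4) at 8 h, 0.09 ± 0.53 at 27 h, -0.02 ± 0.49 at 53 h and 0.56 ± 0.66 at 174 h. On each slide of 53 and 174 h it was higher at 174 h. Replicates 1 to 4 had 0.61, 0.09, -0.50 and -0.28 at 53 h and 1.23, 0.27, -0.22 and 0.96 at 174 h. All counts above are relative to the bulk of the transcripts on each array. Of 19 identifier stems with 2 probes, 10 had both tested, and 8 of these had the same sign at 174 h. Both probes were called there in 6 stems, in the same direction in 5. The meaning of the identifiers' suffixes is unknown, and each identifier was counted as a transcript of its own.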
